A study of Homo sapiens with 6 samples.

How the data were processed

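VCaP is an established human prostate cancer cell line that carries a TMPRSS2-ERG gene fusion. The 6 samples are VCaP cultures with an inducible short hairpin RNA (shRNA), in 3 groups of 2 arrays. The groups are a non-targeting control hairpin (NTC shRNA), PRMT5 shRNA 1 and PRMT5 shRNA 2. PRMT5 is an arginine methyltransferase. All cultures, the control group included, received 100 ng/ml doxycycline for 3 days, so the comparisons are between hairpins and not between induced and uninduced cells. Per the labels' protocols, total RNA was isolated on columns with DNase digestion, amplified, labelled with biotin and hybridised. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

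The deposited values are probe set intensities on a linear scale for 54675 probe sets, made with MAS5 per the submitters' processing notes. The version, any detection call and any later step are not given in the sources used here. In each of the 6 deposited columns the mean intensity after trimming 2% of the values at each end was about 150, so the arrays had been scaled to an equal trimmed mean, and no further scaling was applied. The number of value columns that matched no sample was 0. Array medians lay between 14.8 and 16.4, so many probe sets sat near the background. The number of arrays limits the precision, and the median standard deviation between replicates of a tested gene was 0.08 on the log2 scale. No genome build is given with the values, and no coordinates are reported.

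Probe sets were named through the platform's annotation. Of the non-control probe sets, 41091 had 1 gene symbol, 1801 had several, and 11721 had none or were not listed. Entrez IDs matched 41037 of the first class to the RefSeq gene table of GRCh38.p14, which changed 0 symbols. The 62 control probe sets were left out of all tests. A probe set was kept if its intensity reached the median of its array in at least 2 of the 6 arrays. For each gene the kept probe set with exactly 1 symbol and the highest mean was used, which left 12413 genes. Probe sets without a single symbol were tested in the same way, and are described apart from the genes.

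Values were transformed as log2(intensity + 16) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend). All 6 arrays entered the fit with a coefficient per group, which left 3 residual degrees of freedom and a prior of 7.91. The contrasts were the mean of both PRMT5 shRNAs against NTC, each PRMT5 shRNA against NTC, and PRMT5 shRNA 2 against PRMT5 shRNA 1. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. Thresholds of 2-fold refer to the log2(intensity + 16) scale. Log2 differences are given with the standard error (SE) of limma's moderated fit, and intensities as mean and standard deviation (SD) of 2 arrays. In simulated arrays of the same 12413 genes, each with 200 planted changes, the averaged contrast recovered 68.7% of changes of 0.5 on the log2 scale, 91.0% of changes of 1 and 100% of changes of 2. For PRMT5 shRNA 1 those shares were 58.2%, 91.0% and 100%, for PRMT5 shRNA 2 they were 64.2%, 92.5% and 100%, and for the contrast between the hairpins 58.2%, 88.1% and 100%. False calls made up 2.38% to 4.47% of the calls in these simulations, and 0 genes were called in any of the contrasts where nothing was planted. Far fewer genes were planted than were called in the data, so the shares recovered do not carry over directly. Noise was drawn independently for each gene and array, so these simulations cannot show false calls from an effect shared by genes of an array.

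The likeness of the PRMT5 shRNA profiles was described by the correlation and covariance over genes of their log2 differences from NTC, beside the mean of 100 simulations of unchanged groups sharing the same controls. Genes are not independent replicates, so no p is attached to it. The simulated covariance carries the part due to the shared controls, as far as the spread between replicates measures it. The controls cannot be split into separate sets of 2 arrays, so part of the excess of shared calls over independent lists may come from the shared controls.

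The 26 gene lists covered androgen-induced, androgen-repressed and ERG or ETS genes. They also covered prostate luminal, basal epithelial, neuroendocrine, and stromal, endothelial and immune markers, mesenchymal genes, PRMT5 partners and Sm proteins, other arginine methyltransferases and splicing factors. The cell cycle lists were G1/S genes, G2/M genes, and cell cycle inhibitors with G1 cyclins. The remaining lists were p53 targets, interferon-stimulated genes, ATF4 and unfolded protein response genes, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, ribosome biogenesis, homologous recombination and Fanconi genes, immediate early genes, NF-kB and inflammatory genes, oxidative phosphorylation, and autophagy and lysosome genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The alternatives were camera with an estimated correlation and limma's fry. With an estimated correlation, camera's test is limited to the 3 residual degrees of freedom. A list can then hardly pass after adjustment over 26 lists, so a failure to pass says little. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Members were counted as changed by the test over all genes, and also with p adjusted over the list alone.

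Genes are named by a fixed rule. For the averaged contrast these are the 10 highest and 10 lowest log2 differences among changed genes whose 4 PRMT5 shRNA arrays all lie on the same side of both NTC arrays. For each other contrast they are the 5 highest and 5 lowest whose groups do not overlap. Up to 4 members of each list with the smallest p, and 15 genes chosen for VCaP cells and PRMT5, are always reported. Of those 15, 13 were tested and 2 were not analysed here. Members named beyond the rule to describe a list were chosen after their values were seen.

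The design, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 1 and 64, no filter on dim probe sets and a filter at percentile 75, quantile normalization, centring on the array median, eBayes without the trend and with robust estimation, the mean over a gene's probe sets, and leaving out probe sets whose names end in _x_at or _s_at. Further alternatives were the replicate number as a block, each array left out in turn, only the arrays compared, both PRMT5 shRNAs as 1 group, and unshared controls. A threshold of at least 2-fold, a crossed pairing of replicate numbers, leaving arrays out of the likeness, and lists without paralogs were chosen after seeing the data. Groups of 2 arrays allow no test for an outlying array and no count of other groupings.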

Results

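Gene expression was measured on 54675 probe sets in VCaP prostate cancer cells with a non-targeting hairpin or with either of 2 hairpins against PRMT5, 3 days after induction. Each of the 3 groups held 2 arrays. Over the 12413 genes tested, arrays of the same group correlated at 0.997 (NTC), 0.997 (PRMT5 shRNA 1) and 0.996 (PRMT5 shRNA 2). Arrays of different groups correlated at 0.976 to 0.991. The first principal component held 64.1% of the variance and the second 22.4%. Of the control probe sets for RNA quality, the ratio of 3' to 5' signal of GAPDH was 1.29 ± 0.0531 (SD, n = 2) with NTC, 1.22 ± 0.0177 with PRMT5 shRNA 1 and 1.22 ± 0.00730 with PRMT5 shRNA 2. The ratio for ACTB differed more, at 4.73 ± 0.209 with NTC, 3.69 ± 0.279 with PRMT5 shRNA 1 and 5.36 ± 0.511 with PRMT5 shRNA 2 (SD, n = 2).

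The targeted gene was examined first, as a check on the labels. PRMT5 intensity on its brightest probe set was 845 ± 50 (SD, n = 2) with NTC, 135 ± 1.27 with PRMT5 shRNA 1 and 306 ± 21.1 with PRMT5 shRNA 2. PRMT5 signal was therefore 15.9% of the control value with the first hairpin and 36.2% with the second. The other probe sets gave 16.7% and 36.3%, and 15.3% and 33.3%, respectively. In limma's fit PRMT5 fell with both hairpins averaged (log2 difference -1.97 ± 0.07 SE, adjusted p = 6.5e-09), and it was lower in all 4 knockdown arrays. PRMT5 was higher with shRNA 2 than with shRNA 1 by 1.09 ± 0.08 (SE) on the log2 scale (limma, adjusted p = 7.8e-05).

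**Figure D1:**
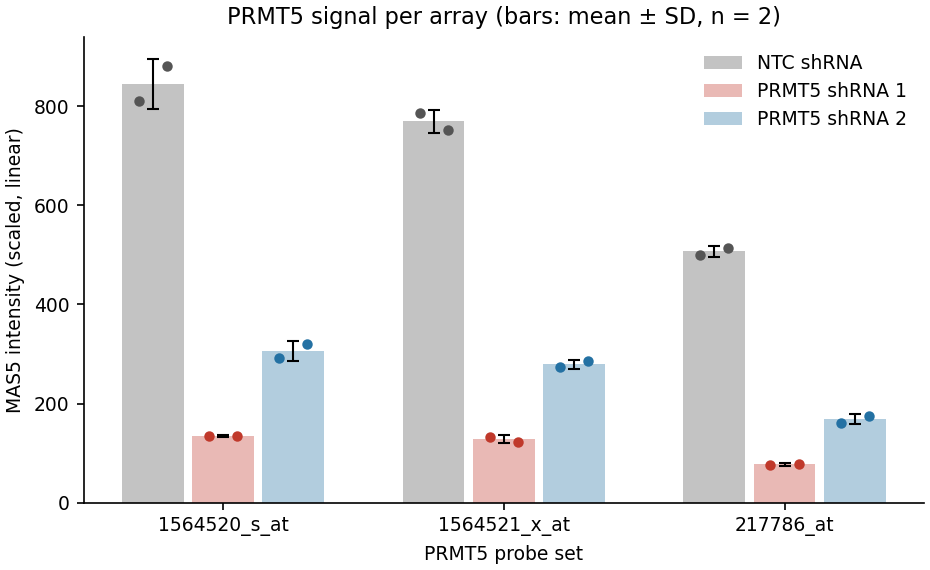
PRMT5 intensity (MAS5, linear scale) for its 3 probe sets in each array; bars are group means, error bars the SD of 2 arrays and points the arrays. In each probe set the NTC arrays lie highest, those of PRMT5 shRNA 1 lowest (15.3% to 16.7% of control) and those of PRMT5 shRNA 2 between them (33.3% to 36.3%).

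The main comparison asked which genes change after PRMT5 knockdown, taking the mean of both hairpins against NTC. XK, a membrane protein that carries a blood group antigen, rose by 3.48 ± 0.07 (SE) on the log2(intensity + 16) scale, from 56.5 ± 3.39 (SD, n = 2) to 714 ± 49.1 with PRMT5 shRNA 1 and 876 ± 22.6 with PRMT5 shRNA 2. BASP1, a membrane-attached signalling protein, rose by 3.38 ± 0.08, from 28.4 ± 0.778 to 523 ± 12.3 and 384 ± 34.6. TGFB2, a ligand of the TGF-beta family, rose by 2.89 ± 0.08, from 42.0 ± 4.17 to 596 ± 14.6 and 284 ± 18.0. RFX6, a transcription factor of endocrine cells, fell by 3.09 ± 0.12, from 234 ± 15.3 to 10.4 ± 1.48 and 16.9 ± 6.36. HDAC9, a class IIa histone deacetylase, fell by 2.93 ± 0.09, from 287 ± 2.83 to 25.8 ± 0.495 and 21.9 ± 3.04. The added 16 makes these differences smaller than those between the intensities themselves, most of all for dim genes.

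The other genes with the highest log2 differences were SPRY4, an inhibitor of receptor tyrosine kinase signalling (2.79 ± 0.09 SE), TGM4, a transglutaminase secreted by the prostate (2.78 ± 0.09), and VSTM2A (2.68 ± 0.08). The extracellular matrix genes LAMA2 (2.96 ± 0.10) and FBLN2 (2.64 ± 0.07) and the peptide transporter SLC15A2 (2.62 ± 0.07) were also among them. LAMA2, VSTM2A and TGM4 in control cells, and RFX6, TCIM and (with shRNA 1) ART3 in knockdown cells, had intensities near or below the array medians of 14.8 to 16.4. The size and rank of their differences therefore depend on the pseudocount. With pseudocounts of 1 and 64 LAMA2 gave 3.46 and 1.55, RFX6 -4.07 and -1.94, and TCIM -3.72 and -1.56, with calls and directions kept. Brighter genes also moved between these pseudocounts, with HDAC9 at -3.54 and -2.00, ESRRG at -2.82 and -1.47, SPRY4-IT1 at 3.60 and 1.91, BASP1 at 3.93 and 2.47, and SPRY4 at 3.25 and 1.99. Among list members, ATF3, CHAC1, CDH2, FADS2 and CXCL1 in control cells and PLAT, SCG2 and FBN1 in knockdown cells lay as low. The transcript SPRY4-IT1 (2.89 ± 0.11) overlaps SPRY4, and the array's probes may not separate the pair. The other genes with the lowest differences were ART3 (-2.98 ± 0.09), the chemokine CXCL11 (-2.79 ± 0.07), SAMD5 (-2.77 ± 0.08), TCIM (-2.68 ± 0.10) and IL1RAPL1, of the interleukin 1 receptor family (-2.66 ± 0.10). They also included the pseudogene NPY6R (-2.37 ± 0.06), the orphan nuclear receptor ESRRG (-2.27 ± 0.11) and the glutamate receptor subunit GRIA2 (-2.16 ± 0.10). For these 20 genes, all 4 knockdown arrays lay on the same side of both control arrays, and limma's adjusted p was at most 6.3e-08 (ESRRG).

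In all, limma called 4027 of 12413 genes (32.4%), with 1914 higher and 2113 lower after knockdown, and a median absolute log2 difference of 0.35 among them. At least 2-fold changes were seen for 253 of them, 163 higher and 90 lower. Without NTC replicate 1 the count of called genes was 2177 (1166 higher, 1011 lower), and without NTC replicate 2 it was 2273 (1242 higher, 1031 lower). The size of the count and its lean toward lower genes were therefore not kept with either control array left out. The median log2 difference of all genes moved little, from -0.0148 to -0.0160 and -0.0116, respectively. Fewer arrays also lower the power, so these counts do not show a dependence on the control arrays themselves. With both hairpins treated as 1 group, whose spread then includes the differences between hairpins, 1505 genes were called, 891 higher and 614 lower. Without PRMT5 shRNA 1 replicate 2 the split was 1611 higher and 1605 lower.

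Genes of the hypoxia and glycolysis list rose together. Of 27 tested members, 22 rose, 1 fell and 4 did not pass (24 rose and 1 fell with p adjusted over the list alone), and 23 were higher with each hairpin. ADM, which encodes the vasodilator adrenomedullin, rose by 1.28 ± 0.07 (SE) on the log2 scale, and PFKFB4, a regulator of glycolysis, by 1.15 ± 0.06. ANKRD37 (0.97 ± 0.06), the aldolase gene ALDOC (0.87 ± 0.07) and the angiogenic factor VEGFA (0.81 ± 0.09) rose as well, while the hexokinase gene HK1 fell (-0.33 ± 0.06), with a call for shRNA 1 only. The list passed limma's camera (adjusted p = 6.9e-11), with adjusted p = 0.135 with an estimated correlation.

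ATF4 and unfolded protein response genes also rose, with 16 of 28 tested members higher, 1 lower and 11 not passing (the same counts of 16 and 1 with p adjusted over the list alone). The largest changes were in SLC7A11, the cystine transporter (1.59 ± 0.08, SE), DDIT4, an inhibitor of mTORC1 (1.01 ± 0.06), ATF3 (0.88 ± 0.11), CHAC1, which degrades glutathione (0.85 ± 0.10), and CEBPB (0.72 ± 0.07). HYOU1, a chaperone of the endoplasmic reticulum, fell (-0.20 ± 0.06), and the chaperone gene HSPA5 (-0.01 ± 0.04) and ATF4 itself (0.05 ± 0.06) did not pass. The camera adjusted p was 2.4e-06, and limma's adjusted p = 0.135 with an estimated correlation. Immediate early genes showed 8 of 19 members higher, 1 lower and 10 not passing (8 and 1 with p adjusted over the list alone). KLF4 (0.89 ± 0.08), EGR1 (0.58 ± 0.07) and FOSL2 (0.48 ± 0.07) rose, and DUSP5, a phosphatase that inactivates ERK, fell (-0.32 ± 0.11). HYOU1, FOSL2 and DUSP5 were called with shRNA 1 but not with shRNA 2. This list passed camera (adjusted p = 0.00623; adjusted p = 0.288 with an estimated correlation), but not with the mean over probe sets (camera adjusted p = 0.0712) or without _x_at and _s_at probe sets (0.169).

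Ribosome biogenesis genes fell, with 0 of 26 members higher, 14 lower and 12 not passing (16 lower with p adjusted over the list alone). NOP2, a methyltransferase of ribosomal RNA, fell by 0.59 ± 0.08 (SE) on the log2 scale, NAT10 by 0.46 ± 0.07, LYAR by 0.41 ± 0.07, and POLR1B, a subunit of RNA polymerase I, by 0.34 ± 0.06. The averaged fall of NAT10 came from shRNA 1 (-0.90 ± 0.08, against -0.02 ± 0.08 with shRNA 2). The camera adjusted p was 0.000295, and limma's adjusted p = 0.288 with an estimated correlation. Among G1/S genes, 0 of 29 rose, 10 fell and 19 did not pass (10 lower with p adjusted over the list alone). CDC25A, a phosphatase that activates cyclin-dependent kinases, fell by 0.50 ± 0.06, the replicative helicase subunits MCM2 by 0.37 ± 0.06 and MCM3 by 0.31 ± 0.06, and MCM10 by 0.29 ± 0.05. MCM3 was called with shRNA 1 (-0.54 ± 0.07) and not with shRNA 2 (-0.08 ± 0.07). Their camera adjusted p was 0.00225 and limma's adjusted p = 0.288 with an estimated correlation.

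G2/M genes had 7 of 31 members lower and 0 higher, by both adjustments, among them CDC25B (-0.39 ± 0.05, SE), the centromere protein CENPF (-0.30 ± 0.06), TTK (-0.23 ± 0.06) and BUB1 (-0.22 ± 0.06), and did not pass camera (adjusted p = 0.266). CENPF, TTK and BUB1 were called with shRNA 1 but not with shRNA 2, and TTK and BUB1 lost their averaged call without either control array. BUB1 also lost it with the mean over probe sets. Of 14 cell cycle inhibitors and G1 cyclins, 2 rose and 1 fell by both adjustments (camera adjusted p = 0.412). CDKN1C (0.55 ± 0.09) and CDKN1A (0.54 ± 0.08) rose and RBL1 fell (-0.29 ± 0.06), while CDKN2B (0.28 ± 0.11) did not pass. Of 20 p53 targets, 4 rose and 4 fell (5 and 5 with p adjusted over the list alone; camera adjusted p = 0.964). FAS, a death receptor, fell (-0.99 ± 0.06), as did GADD45A (-0.36 ± 0.06), and GDF15 rose (0.51 ± 0.09). Homologous recombination and Fanconi genes had 2 members higher and 7 lower of 22 (3 and 11 with p adjusted over the list alone; camera adjusted p = 0.0988). FANCI (-0.30 ± 0.06) and BLM (-0.27 ± 0.06) fell, and RAD54B (0.27 ± 0.05) and NBN (0.21 ± 0.05) rose, both called with shRNA 1 only. RBL1 and RAD54B lost their averaged call without NTC replicate 1, and BLM and NBN without NTC replicate 2.

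Androgen-induced genes went both ways, with 12 of 31 members higher, 6 lower and 13 not passing (14 and 6 with p adjusted over the list alone). KLK3, which encodes prostate-specific antigen, rose by 1.13 ± 0.05 (SE) on the log2 scale, from 1178 ± 12.4 (SD, n = 2) to 2626 ± 55.4 with PRMT5 shRNA 1 and 2570 ± 148 with PRMT5 shRNA 2. EAF2, a transcription elongation factor (1.70 ± 0.07, SE), the prostaglandin receptor PTGER4 (1.49 ± 0.07), the metalloreductase STEAP4 (1.03 ± 0.07) and SLC45A3 (0.63 ± 0.05) rose, and the transcription factor MAF (-0.81 ± 0.09) and the kinase CAMKK2 (-0.40 ± 0.06) fell. KLK2 rose by 0.16 ± 0.05, and TMPRSS2 (-0.21 ± 0.07) and FKBP5 (-0.14 ± 0.05) fell slightly. The list passed camera (adjusted p = 0.00605; adjusted p = 0.399 with an estimated correlation), but not without _x_at and _s_at probe sets (camera adjusted p = 0.0696). KLK genes resemble each other in sequence, so the values of KLK2 and KLK3 are uncertain.

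Of 11 androgen-repressed genes, 2 rose and 5 fell (2 and 6 with p adjusted over the list alone), and the list did not pass camera (adjusted p = 0.121). The glucuronosyltransferase genes UGT2B28 (-1.67 ± 0.11, SE), UGT2B15 (-1.23 ± 0.07) and UGT2B17 (-1.17 ± 0.09) and the opioid receptor OPRK1 (-1.18 ± 0.09) fell, and the cadherin CDH2 rose (1.18 ± 0.13). The UGT2B genes are close paralogs whose probes may cross-hybridise, and without _x_at and _s_at probe sets UGT2B15 did not pass (-0.16, limma, adjusted p = 0.536). FOLH1, which encodes prostate-specific membrane antigen, did not pass (0.07 ± 0.06).

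Genes reported higher with ERG or other ETS factors also moved both ways, with 5 of 20 higher and 9 lower by both adjustments (camera adjusted p = 0.362). With shRNA 1 alone 5 rose and 10 fell, and with shRNA 2 alone 4 rose and 4 fell. PLAT, a plasminogen activator (-1.07 ± 0.11, SE), CACNA1D, a calcium channel subunit (-0.88 ± 0.08), and ARHGDIB (-0.77 ± 0.05) fell, and the chemokine receptor CXCR4 (1.04 ± 0.10) and NCALD (0.63 ± 0.06) rose. ERG itself fell by 0.21 ± 0.06 on the log2 scale (limma, adjusted p = 0.020), and EZH2, a histone methyltransferase, by 0.18 ± 0.06 (limma, adjusted p = 0.037). MYC (-0.03 ± 0.07) and FOXA1 (-0.13 ± 0.08) did not pass. The small changes of ERG, EZH2, KLK2, TMPRSS2 and FKBP5 each lost their call when either control array was left out, except that TMPRSS2 kept it without NTC replicate 1. All 5 were called with shRNA 1 and not with shRNA 2.

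Prostate luminal markers had 5 of 15 members higher and 1 lower by both adjustments. The keratin genes KRT19 (1.26 ± 0.09, SE), KRT8 (0.58 ± 0.07) and KRT18 (0.27 ± 0.07) and the tight junction gene CLDN4 (0.49 ± 0.08) rose, and the transcription factor HOXB13 fell (-0.28 ± 0.07), although its other probe set had the opposite sign. The list passed camera (adjusted p = 0.0358; adjusted p = 0.551 with an estimated correlation), but not after quantile normalization (camera adjusted p = 0.0984) or without _x_at and _s_at probe sets (0.169). Without NTC replicate 1, PRMT5 shRNA 1 replicate 2 or PRMT5 shRNA 2 replicate 1 the camera adjusted p was 0.0556, 0.0827 and 0.0764. Of 6 basal epithelial markers, only ITGA6 changed, by both adjustments (-0.20 ± 0.05, camera adjusted p of the list = 0.749). CD44 (0.19 ± 0.07) and DST (0.08 ± 0.05) did not pass. The mean over probe sets called both higher (0.28 and 0.17, limma, adjusted p = 0.0155 and 0.0260). All other kept probe sets of CD44 and DST had the same sign. Of 13 neuroendocrine markers, 1 rose and 3 fell by both adjustments (camera adjusted p = 0.314). These were SYT4 (0.27 ± 0.05) and NCAM1 (-0.54 ± 0.10), INSM1 (-0.43 ± 0.06) and SCG2 (-0.42 ± 0.12). Of the markers named, KRT18, HOXB13, ITGA6, SYT4, NCAM1 and SCG2 were called with shRNA 1 but not with shRNA 2. Their averaged calls were lost without either control array for ITGA6, without NTC replicate 1 for SCG2 and without NTC replicate 2 for HOXB13. SCG2 also lost its call without PRMT5 shRNA 1 replicate 2 or PRMT5 shRNA 2 replicate 1. HOXB13 also lost its call with the mean over probe sets (-0.14, limma, adjusted p = 0.111).

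Of 5 mesenchymal genes above the filter, 3 rose and 0 fell by both adjustments, namely TGFB2, the collagen cross-linking enzyme LOX (0.65 ± 0.11, SE) and CCN1 (0.31 ± 0.09), while FN1 did not pass (0.07 ± 0.11). CCN1 was called with shRNA 2 only, and lost its averaged call without either control array and with the mean over probe sets. The list passed camera (adjusted p = 0.0209; adjusted p = 0.288 with an estimated correlation), but not with no filter on dim probe sets (camera adjusted p = 0.288) or without _x_at and _s_at probe sets (0.0868). Of 5 stromal, endothelial and immune markers, 2 rose and 2 fell by both adjustments (camera adjusted p = 0.904), and the list's median (0.10) and mean (-0.08) differed in sign. ACTA2, smooth muscle actin (-1.60 ± 0.09), and FBN1, fibrillin (-1.10 ± 0.10), fell, and LYZ, lysozyme (1.34 ± 0.09), and LUM, lumican (0.87 ± 0.07), rose.

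**Figure D2:**
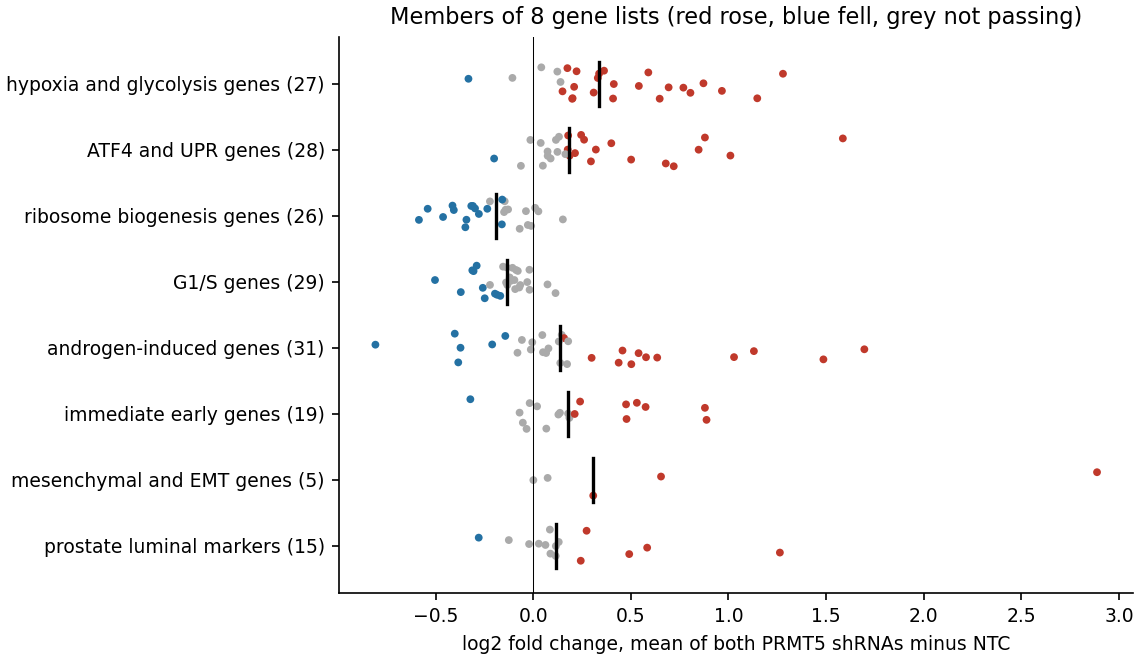
Log2 difference of the mean of both PRMT5 shRNAs from NTC for each tested member (points) of the 8 lists that passed camera, with the number of members in parentheses and a black bar at the list's median. Members that rose are red, those that fell blue and those that did not pass grey; medians run from -0.19 for ribosome biogenesis to 0.34 for hypoxia and glycolysis genes.

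The lists close to the function of PRMT5 did not pass camera. PRMT5 methylates Sm proteins of the spliceosome together with WDR77. Of 20 tested partners and Sm proteins, 0 rose and 6 fell by both adjustments, among them LSM11 (-0.54 ± 0.08, SE), GEMIN4 (-0.37 ± 0.07), GEMIN5 (-0.35 ± 0.07) and RIOK1 (-0.34 ± 0.09), and WDR77 did not pass (-0.09 ± 0.05; camera adjusted p of the list = 0.284). Of 7 other arginine methyltransferases, 0 rose and 2 fell by both adjustments (PRMT2, -0.42 ± 0.11, and PRMT3, -0.29 ± 0.08; camera adjusted p = 0.255). Limma's fry called both of these lists downward (adjusted p = 0.0325 for the partners and 0.0142 for the methyltransferases). With shRNA 2 alone fry called neither (adjusted p = 0.0609 and 0.0864). Of 35 splicing factors, 0 rose and 6 fell (1 with p adjusted over the list alone), led by PRPF8 (-0.33 ± 0.06), SRSF4 (-0.25 ± 0.07), SNRPA (-0.20 ± 0.06) and SNRNP70 (-0.22 ± 0.07; camera adjusted p of the list = 0.321). SRSF4 lay higher than NTC with shRNA 1 (0.18 ± 0.08) and fell with shRNA 2 (-0.67 ± 0.08), and SNRPA was called with neither hairpin alone. GEMIN4, RIOK1, PRMT2, PRMT3, PRPF8 and SNRNP70 were called with shRNA 1 but not with shRNA 2. Averaged calls were lost without either control array for SRSF4 and SNRPA, without NTC replicate 1 for PRMT2 and PRMT3, and without NTC replicate 2 for RIOK1 and SNRNP70. SRSF4, PRMT2 and SNRNP70 also lost them with the mean over probe sets, and SNRNP70 in several other settings.

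Of 18 cholesterol synthesis genes, 7 rose and 2 fell by both adjustments (camera adjusted p = 0.0839). SC5D (0.74 ± 0.06, SE), TM7SF2 (0.49 ± 0.07) and MSMO1 (0.38 ± 0.05) rose, and LSS, lanosterol synthase, fell (-0.29 ± 0.06). Of 15 fatty acid synthesis genes, 3 rose and 4 fell (4 and 4 with p adjusted over the list alone; camera adjusted p = 0.964), and the median (-0.08) and mean (0.01) differed in sign. The desaturase gene FADS2 (0.83 ± 0.12) and ME1 (0.37 ± 0.08) rose, and FASN, fatty acid synthase, fell (-0.43 ± 0.07). Of 22 autophagy and lysosome genes, 7 rose and 1 fell (8 and 1 with p adjusted over the list alone; camera adjusted p = 0.121), with GABARAPL1 at 0.41 ± 0.11, WIPI1 at 0.40 ± 0.09 and CTSB, cathepsin B, at 0.23 ± 0.06. HEXA rose as well (0.28 ± 0.07), but its direction turned with the choice of probe set. Only 1 of 3 other probe sets of CTSB had the same sign, and with the mean over probe sets CTSB did not pass (0.08, limma, adjusted p = 0.304). Of 27 oxidative phosphorylation genes, 0 rose and 2 fell (0 and 0 with p adjusted over the list alone; camera adjusted p = 0.715), UQCRC2 (-0.17 ± 0.05) and SDHA (-0.15 ± 0.05). LSS, UQCRC2 and SDHA were called with shRNA 1 only, and ME1 and GABARAPL1 with shRNA 2 only. UQCRC2 also lost its averaged call with the mean over probe sets. UQCRC2, SDHA and HEXA lost it without either control array, and WIPI1 and CTSB without NTC replicate 1.

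Of 19 interferon-stimulated genes, 5 rose and 2 fell by both adjustments (camera adjusted p = 0.472). HERC5 (0.43 ± 0.10, SE) and IFI44 (0.43 ± 0.09) rose, and the transcription factor IRF7 (-0.50 ± 0.11) and OAS3 (-0.41 ± 0.07) fell. Of 11 NF-kB and inflammatory genes, 5 rose and 2 fell by both adjustments (camera adjusted p = 0.382). NFKBIA, the inhibitor of NF-kB, rose (0.64 ± 0.09), as did TNFAIP2 (0.41 ± 0.06) and CXCL1 (0.46 ± 0.10), and the chemokine CXCL10 fell (-1.19 ± 0.09). HERC5, IRF7 and OAS3 were called with shRNA 1 only, and IFI44 with shRNA 2 only. HERC5, IFI44 and CXCL1 lost their averaged call without NTC replicate 2, and IFI44 and NFKBIA without _x_at and _s_at probe sets. In all, 8 of the 26 lists passed camera with the preset correlation. With an estimated correlation 0 lists passed camera, 3 had an unadjusted p under 0.05, and fry called 17. With 3 residual degrees of freedom that 0 was close to fixed by the number of arrays, and says little about the 8 lists. Beyond the 8, fry called cholesterol synthesis and NF-kB genes upward. It called downward the androgen-repressed, ERG or ETS and G2/M genes, the basal and the stromal, endothelial and immune markers, PRMT5 partners and other arginine methyltransferases. With shRNA 2 alone fry called neither the ERG or ETS (adjusted p = 0.860) nor the basal list (0.151). It also did not call NF-kB genes (0.0609), PRMT5 partners (0.0609) or other arginine methyltransferases (0.0864) with that hairpin.

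Each hairpin was also compared with NTC alone, to ask which changes occur with both. With PRMT5 shRNA 1 the 5 highest log2 differences were those of BASP1 (3.60 ± 0.09, SE), TGFB2 (3.40 ± 0.09), SPRY4-IT1 (3.39 ± 0.13), XK (3.33 ± 0.08) and SPRY4 (3.08 ± 0.10). The 5 lowest were those of ART3 (-3.36 ± 0.10), RFX6 (-3.24 ± 0.14), CXCL11 (-3.21 ± 0.08), IL1RAPL1 (-2.95 ± 0.11) and SAMD5 (-2.91 ± 0.09). With PRMT5 shRNA 2 the highest were XK (3.62 ± 0.08), BASP1 (3.17 ± 0.09), LAMA2 (3.12 ± 0.12), FBLN2 (2.86 ± 0.08) and TGM4 (2.83 ± 0.11). The lowest were HDAC9 (-3.00 ± 0.10), RFX6 (-2.94 ± 0.14), SAMD5 (-2.63 ± 0.09), ART3 (-2.60 ± 0.10) and TCIM (-2.56 ± 0.12). The values of RFX6, TCIM, LAMA2 and TGM4, and of ART3 with shRNA 1, rest on an intensity near or below the array median in 1 of the groups compared, so their size and rank depend on the pseudocount.

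PRMT5 shRNA 1 changed 4883 genes in limma (39.3%; 2008 higher, 2875 lower), and PRMT5 shRNA 2 changed 2668 (21.5%; 1623 higher, 1045 lower). At least 2-fold changes numbered 318 (187 higher, 131 lower) and 234 (164 higher, 70 lower), so the lean of PRMT5 shRNA 1 toward lower genes was not seen among them. With median centring the splits were 1635 higher and 3369 lower for PRMT5 shRNA 1, and 1768 higher and 900 lower for PRMT5 shRNA 2. With PRMT5 shRNA 1 the same 8 lists passed camera as in the averaged contrast, and cholesterol synthesis in addition (adjusted p = 0.0386). With PRMT5 shRNA 2 camera also called the androgen-repressed genes downward (adjusted p = 0.0178), homologous recombination and Fanconi genes downward (adjusted p = 0.0192), and autophagy and lysosome genes upward (adjusted p = 0.0285), but not the luminal markers (adjusted p = 0.0879). With an estimated correlation 0 lists passed for either hairpin, and 3 had an unadjusted p under 0.05 in each. Leaving out NTC replicate 1 gave 3181 genes for PRMT5 shRNA 1 and 1553 for PRMT5 shRNA 2, and leaving out PRMT5 shRNA 1 replicate 2 gave 3183 for that hairpin. Leaving out NTC replicate 2 gave 1675 genes for PRMT5 shRNA 2.

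Both hairpins called 1796 genes in the same direction, which is 67.3% of the genes called with PRMT5 shRNA 2. Of these, 1037 were higher, where independent lists would share 263, and 759 were lower, where independent lists would share 242. Opposite directions were seen for 34 genes, where independent lists would give 545. The values for independent lists leave out that both contrasts share the NTC arrays. Simulated groups without effects that share them gave 0 shared genes, but limma called 0 genes in either simulated contrast, so this 0 says little about the overlap. At least 2-fold changes in both contrasts numbered 194, and without NTC replicate 1 or 2 the shared count was 1097 and 1182. Across genes, the log2 differences of the hairpins correlated at r = 0.788 (Spearman's rho 0.616), against 0.502 in simulated groups without effects. Their covariance was 0.101 against a simulated 0.00578, a difference of 0.0956. With a separate control array for each hairpin, r was 0.720 or 0.717. Among the genes called with both in the same direction, the slope of shRNA 2 on shRNA 1, through the origin, was 0.856. That choice leaves out genes called with only 1 hairpin, so the slope does not describe all genes changed by shRNA 1.

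**Figure D3:**
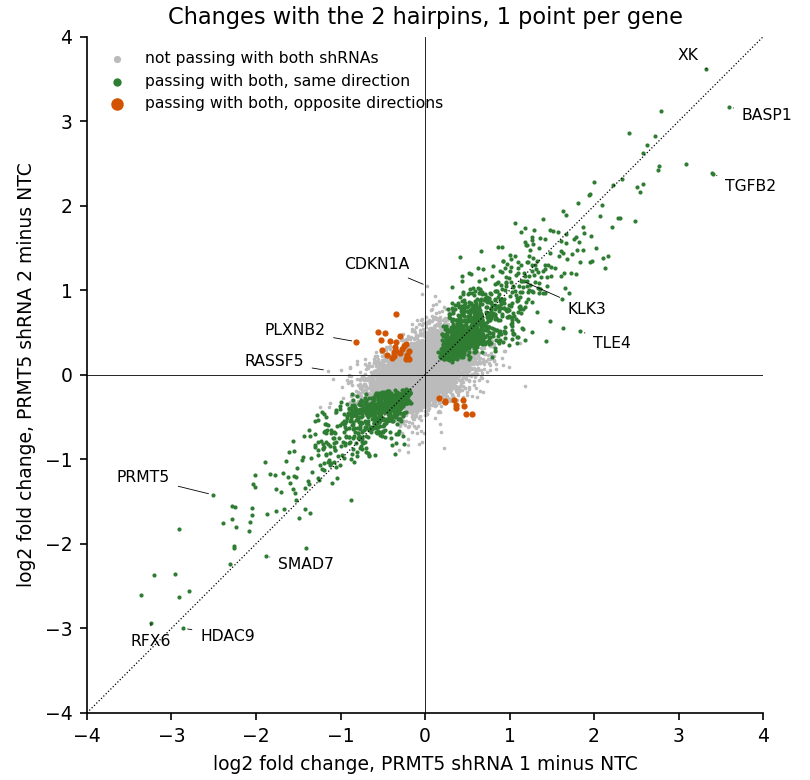
Log2 difference from NTC with PRMT5 shRNA 2 (vertical axis) against that with PRMT5 shRNA 1 (horizontal axis), 1 point per gene; the dotted line marks equal values. The 1796 genes called with both in the same direction (green) lie along the line, and 34 genes called in opposite directions (orange) lie off it near the centre.

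The hairpins were then compared directly, which tests whether their effects differ. Higher with PRMT5 shRNA 2 were PLXNB2, a semaphorin receptor, at 77.0 ± 0.566 (SD, n = 2) with shRNA 1, 200 ± 21.8 with shRNA 2 and 149 ± 16.8 with NTC, and RASSF5, a Ras effector, at 165 ± 9.90, 400 ± 11.6 and 386 ± 11.2. The peroxisomal oxidase gene ACOX2 was higher by 1.06 ± 0.10 (SE) on the log2 scale, and PRMT5 and NPY6R by 1.09 ± 0.08 and 1.08 ± 0.07. Higher with PRMT5 shRNA 1 were TLE4, a transcriptional corepressor, at 217 ± 18.1 with shRNA 1, 76.8 ± 1.34 with shRNA 2 and 49.8 ± 14.6 with NTC, and INHBA, which encodes a subunit of activin (-1.30 ± 0.16 SE for shRNA 2 minus shRNA 1). BMS1P20, a pseudogene (-1.09 ± 0.10), OSR1, a transcription factor (-1.08 ± 0.12), and MUCL1, a mucin-like protein (-1.04 ± 0.10), were also higher with shRNA 1. CDKN1A, the cyclin-dependent kinase inhibitor p21, was 436 ± 33.4 with NTC, 443 ± 2.26 with shRNA 1 and 925 ± 142 with shRNA 2 (SD, n = 2), so its averaged change came from shRNA 2 (difference 1.03 ± 0.10 SE; limma, adjusted p = 0.00021). ERG was 1407 ± 56.2 with NTC, 1065 ± 85.1 with shRNA 1 and 1390 ± 49.2 with shRNA 2, a difference between hairpins of 0.38 ± 0.07 (limma, adjusted p = 0.0034).

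limma called 3192 genes different between the hairpins (25.7%), of which 2276 (71.3%) were higher and 916 lower with PRMT5 shRNA 2. At least 2-fold differences numbered 17, and the median absolute log2 difference of the called genes was 0.37. With median centring, which moved the median log2 difference of all genes to 0.11, 84.2% were higher (3241 against 608). With the mean over probe sets 60.9% were higher (2025 against 1299). The ACTB 3' to 5' ratio, which differed between these groups, stood at 3.69 ± 0.279 and 5.36 ± 0.511 (SD, n = 2). The count was 1719 and 1326 without PRMT5 shRNA 1 replicate 1 or 2, and 2033 without PRMT5 shRNA 2 replicate 2.

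No gene list passed camera between the hairpins, with the smallest adjusted p at 0.0576 for oxidative phosphorylation genes (0 higher and 2 lower with shRNA 2). The camera test gave 6 lists an unadjusted p under 0.05, and fry called 5. Among ERG or ETS genes 9 members were higher with shRNA 2 and 1 lower (camera adjusted p = 0.161), among neuroendocrine markers 7 and 1 (camera adjusted p = 0.161), and among ATF4 and unfolded protein response genes 2 and 7 (camera adjusted p = 0.0897).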

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

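The tests of weaker knockdown, of scaling and of RNA integrity were chosen after the differences between the hairpins were seen, and both tests on probe sets without a symbol were written before their outcome was known.

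Hairpins against the same gene differed from each other at 3192 genes, and 34 genes were called in opposite directions against NTC. The largest differences of shRNA 2 minus shRNA 1 were in PLXNB2 (log2 1.21), RASSF5 (1.20), PRMT5 itself (1.09), NPY6R (1.08), ACOX2 (1.06) and CDKN1A (1.03). In the other direction they were in TLE4 (-1.32), INHBA (-1.30), BMS1P20 (-1.09), OSR1 (-1.08) and MUCL1 (-1.04). Each drew attention as a difference between groups meant to share a target, and each rests on 2 arrays per hairpin.

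PRMT5 was reduced less with shRNA 2, and a weaker knockdown would make its changes smaller in the same direction. Of the 3192 genes, 39.6% lay on the same side of NTC with both hairpins and nearer to it with shRNA 2. Another 17.8% (exact 95% interval 16.5% to 19.2%) were changed by shRNA 2 further than, or opposite to, shRNA 1, which argues against weaker knockdown as the whole cause. That interval treats genes as independent, which they are not, and is too narrow. The remaining genes, the largest of these classes, lay further from NTC or on its other side with shRNA 2. They were not called against NTC with that hairpin, so they decide nothing for or against a weaker knockdown. Under the scaling that keeps fewest, 90.1% of the genes keep call and sign, which argues against scaling as the source of most single calls. The share higher with shRNA 2 was 71.3%, against 70.2% with quantile normalization and 84.2% with median centring. Scaling therefore stays open for the lean toward higher genes. RNA integrity cannot be told apart, because the GAPDH 3' to 5' ratio was nearly equal (1.01 for shRNA 2 over shRNA 1) while that of ACTB was not (1.45). Effects of a hairpin on other transcripts were not tested, since the hairpin sequences were not used here, and stay open.

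Probe sets without a single gene symbol also responded, in data outside the gene comparisons. Of 4724 tested, limma called 1126 in the averaged contrast, 499 higher and 627 lower. Between the hairpins it called 1319, with 429 higher and 890 lower with shRNA 2, a lean opposite to that of the named genes. At matched intensity the gap in median log2 difference, named minus unnamed, was 0.130 (95% bootstrap interval 0.120 to 0.144), against 0.117 unmatched, which argues against an intensity-dependent array response. With all probe sets of 1 symbol in place of the brightest the gap was smaller, at 0.0656 (0.0563 to 0.0792). Part of the gap therefore came with the choice of the brightest probe set. A gap remained, but those probe sets still include the brightest ones, so its other sources cannot be told apart. Both intervals treat probe sets as independent and are too narrow.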

How the results depend on the processing

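The threshold of 2-fold, the crossed block and the likeness with arrays left out were tests chosen after seeing the data. PRMT5 fell in every setting (log2 -1.74 to -2.05). Outside left-out arrays, pooled hairpins and the 2-fold threshold, the counts of called genes ran from 2811 to 4281 (averaged), 3488 to 5290 (PRMT5 shRNA 1), 1786 to 3055 (PRMT5 shRNA 2), 2334 to 3849 (between hairpins) and 1229 to 2048 (both, same direction). Without an array they ran from 2177 to 4253, 3181 to 5290, 1553 to 2443, 1326 to 2831 and 1097 to 1736, respectively; a group's remaining array is then assumed to vary like the other groups. The averaged count was 2177 without NTC replicate 1, 2273 without NTC replicate 2 and 1505 with both hairpins as 1 group. PRMT5 shRNA 1 had 3181 without NTC replicate 1 and 3183 without its replicate 2, and PRMT5 shRNA 2 had 1553 and 1675 without NTC replicate 1 or 2. Between hairpins 1719 and 1326 remained without PRMT5 shRNA 1 replicate 1 or 2, and 2033 without PRMT5 shRNA 2 replicate 2; both hairpins shared 1097 and 1182 without NTC replicate 1 or 2. Fewer arrays lower the power by construction. The counts that rose above those of the full data did so only when an array of PRMT5 shRNA 2 was left out. Those rises do not show whether lost power accounts for the falls, which was not tested. The 2-fold threshold left 253, 318, 234, 17 and 194 by construction.

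The likeness was 0.748 to 0.793 with arrays left out (0.767 without PRMT5 shRNA 1 replicate 1 and 0.748 without PRMT5 shRNA 2 replicate 1), and 0.720 and 0.717 with unshared controls. The lists passing camera, 8, became 4 without _x_at and _s_at probe sets, 0 with an estimated correlation, 17 with fry, and 7 to 10 with arrays left out; the cause was not tested. Camera's call of homologous recombination genes was gained with no filter (adjusted p = 0.0460), and those of this list and of cholesterol synthesis without PRMT5 shRNA 2 replicate 2 (adjusted p = 0.0422 each). HEXA turned to -0.0581 with the mean over probe sets and to -0.23 without _x_at and _s_at probe sets, and the stromal list was called downward by fry (adjusted p = 0.0180); the cause was not tested. Of the values of single named genes under the alternatives, 2191 kept direction and call, 113 lost the call, 11 gained it and 2 reversed. The replicate number as a block gave 3711, 4565, 2441, 2845 and 1662. Deviations of equal numbers correlated at -0.0880, -0.177 and -0.00436 between the groups, and a crossed pairing for PRMT5 shRNA 2 gave 2719 genes against 2668. Dim genes are limited by signal over background, with array medians of 14.8 to 16.4.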

Other observations

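The lists of this part and the tests of androgen-linked genes were chosen after the values were seen.

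Genes that respond to bone morphogenetic proteins (BMPs) changed widely. Of 16 tested members, 12 rose and 3 fell in limma's averaged contrast. The transcription factor ATOH8 rose by 2.23 ± 0.07 (SE) on the log2 scale, the inhibitors of DNA binding ID1 and ID3 by 2.08 ± 0.08 and 1.33 ± 0.07, the inhibitory SMAD6 by 1.50 ± 0.09 and the pseudoreceptor BAMBI by 1.19 ± 0.12, whereas SMAD7 fell (-2.02 ± 0.05). Without the 6 members whose values prompted the list, 7 of 10 rose and 2 fell. Their adjusted p over the 7 added lists was 0.00102 in camera, and 0.0815 in camera with an estimated correlation. That adjustment runs over lists whose own values prompted them, which makes it too lenient. These 10 members were also listed after the values were seen, so neither p is independent support. All 3 ligands of the chemokine receptor CXCR3 fell, CXCL11 by 2.79 ± 0.07, CXCL10 by 1.19 ± 0.09 and CXCL9 by 1.03 ± 0.10; no test of this list is given, since its members' values prompted it.

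Nuclear receptors went both ways, with 7 of 27 higher and 7 lower. PPARG (2.07 ± 0.09, SE) and RORB (1.34 ± 0.11) rose, and NR5A2 (-1.76 ± 0.08), the progesterone receptor PGR (-1.63 ± 0.10) and the vitamin D receptor VDR (-1.23 ± 0.07) fell. Of 9 secretory proteins linked to androgen, 5 rose and 3 fell, among them SCGB1D2 (1.61 ± 0.08), SCGB2A1 (1.11 ± 0.07) and KLK4 (-0.41 ± 0.07, called with shRNA 2 only). Of 18 potassium channel subunits, 3 rose and 6 fell, with KCNG3 at -2.14 ± 0.10 and KCNH8 at -2.02 ± 0.07. Of 12 ERK feedback genes, 5 rose and 4 fell, with SPRY4 at 2.79 ± 0.09, DUSP2 at 1.92 ± 0.10 and EPHA4 at -0.56 ± 0.09 (called with shRNA 2 only). Values seen before prompted these 4 lists, so no test of them is given. PPARG in control cells and CXCL9 and PGR in knockdown cells lay below the array medians of 14.8 to 16.4, so the size of their differences depends on the pseudocount. Of 71 gene families by symbol, 0 passed camera (smallest adjusted p = 0.0932), 17 had an unadjusted camera p under 0.05, and 0 had with an estimated correlation.

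Androgen-induced genes passed camera upward (adjusted p = 0.00605; adjusted p = 0.399 with an estimated correlation), although 6 of the 18 changed members fell. Without KLK2 and KLK3 the list still passed camera (adjusted p = 0.0233), which argues against cross-hybridisation of KLK2 and KLK3 as the whole cause. Without _x_at and _s_at probe sets it did not pass (camera adjusted p = 0.0696), so cross-hybridisation of other members stays open. A hypothesis is that PRMT5 knockdown strengthens the androgen response. Of 25 changed members of the androgen-induced and androgen-repressed lists, 17 (68.0%, exact 95% interval 46.5% to 85.1%, genes taken as independent) went with it, and a stronger response cannot be told apart from a mixed change of these genes. Without the UGT2B genes the androgen-repressed list gave a camera adjusted p of 0.940.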
